A study of Mus musculus with 12 samples.

How the data were processed

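Total RNA from mouse liver was sequenced in 12 samples that fall into 3 groups of 4, named by the short hairpin RNA (shRNA) that an adenovirus carried into the animal. The shLacZ group received a hairpin against the bacterial lacZ gene and served as control, and the shG0s2 and shRgs16 groups received hairpins against G0s2 and Rgs16. Per the labels' protocols, the mice were wild-type C57BL/6J animals aged 8 weeks, virus was given into the tail vein, and livers were taken 12 days later at zeitgeber time 12, the change from light to dark, after food had been withheld for 6 h of daytime. RNA was isolated with Trizol, treated with DNase I and depleted of ribosomal RNA, per the labels. The groups and replicate numbers were taken from the sample titles. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples. Within groups, pairs of samples differed by a chi-square per degree of freedom of 12.12 to 47.26, beyond counting noise. That argues against repeat sequencing of the same library. Repeats prepared separately from the same liver stay open, so the spread may still be technical.

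The authors deposited 1 table for each knockdown against shLacZ. Per the file headers, each table gives estimated counts per gene and sample, and between 5789 and 6625 values in a sample were not whole numbers. The same deposited tables hold TPM, transcript abundance corrected for transcript length and scaled to a fixed total, for each sample; the columns sum to 992336 to 996333. They also hold the authors' fold change as a ratio, its log2 value, a p-value and an adjusted p-value. The submitters' processing notes name fastp 0.19.5, Bowtie2 2.2.9, GATK 3.8, SAMtools 1.9 and DESeq2, without saying which step used which. The genome build, the annotation, the program that assigned reads to genes and the strand setting are not given in the sources used here. All 55536 gene identifiers and symbols matched the GENCODE annotation of the mouse reference used here (GRCm38), which supplied the coordinates printed below. Estimated counts split reads among similar genes by a model, so values for near-identical copies such as the major urinary protein (Mup) family are uncertain for each copy. The shLacZ columns held the same values in both tables, with 0 differences over 8 columns compared, so the 12 samples were joined.

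Estimated counts were rounded to whole numbers. Total counts ranged from 18458266 to 27170443 per sample, the lowest being shG0s2 replicate 2. Each knockdown was compared with shLacZ using its 8 samples, and shG0s2 was compared with shRgs16 in a model of all 12 samples. Genes were filtered with filterByExpr, scaled with TMM and tested two-sided with the quasi-likelihood F test of edgeR 4.0.16 (robust fit) in R 4.3.3, with Benjamini-Hochberg adjustment and a false discovery rate of 0.05. Reported log2 fold changes and standard errors come from that model, and every adjusted p without another tool's name is edgeR's. Levels are given as CPM, counts relative to the library total, scaled by TMM within the samples of the comparison, and for the targeted genes and single samples over all 12.

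Before the data were examined, 44 gene lists (pathways, stress responses and cell type markers) were fixed, together with the tests, the alternatives and the rule for naming genes. Lists with 5 or more tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over all lists. Each list was tested again with its estimated correlation and with fry. Members were counted as higher, lower or not past the threshold, over all genes and adjusted over the list alone. The lipid droplet and lipolysis list holds G0s2, the RGS list holds Rgs16, and the glycolysis and ChREBP list holds both. The fall of a gene under its own hairpin is therefore counted among the lower members of those lists. The genes named are G0s2 and Rgs16; the 8 largest increases and 8 largest decreases among genes past the threshold with an official symbol that is not a predicted model or pseudogene, a mean of at least 1 CPM and groups that do not overlap; and up to 2 members of each list with the smallest p. For shG0s2 against shRgs16, and for genes changed in both knockdowns, 4 in each direction were taken. Genes changed in both were ordered by the smaller of their absolute changes, a choice made after the data were seen. Some genes that the rule takes are not reported here.

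The overlap of both knockdowns uses the same controls, so it was set beside 20 simulations of unchanged groups, beside the product expected of independent gene sets, and beside 6 analyses with the controls divided between the comparisons. Alternatives were DESeq2 1.42.0, limma-voom, relative log expression scaling, library size alone, no filter, a filter of 1 CPM in 4 samples, a fold threshold, a replicate block, all samples in the model and each sample left out. Leaving out the Mup genes was added after the data were seen. Words of 7 bases in 3′ untranslated regions were scored for association with fold change by linear regression in Python 3.11.15.

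The methods were tested on simulated counts drawn from the real means and library sizes with 200 genes changed. For shG0s2 against shLacZ (14695 genes run), 56.7% of genes changed by a fold of 1.5, 79.1% of those changed by 2 and 100% of those changed by 4 were recovered, and 5.26% of calls were not planted. For shRgs16 against shLacZ (14734 genes run), the shares were 73.1%, 88.1% and 97.0%, with 4.48% of calls not planted. In both simulations the planted gene list was the 1 list called. Genes were drawn independently of each other, so this cannot show how camera behaves when genes of a list vary together. With the list, 238 and 240 genes were planted, far fewer than the 9430 and 7518 called in the data. The 200 genes were taken above a minimum mean count, and no loss of the Mup family was planted. The shares recovered and falsely called may therefore not carry over to the data.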

Results

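Hepatic RNA was profiled in mice whose livers had been infected with adenovirus carrying a hairpin against lacZ (control), G0s2 or Rgs16, with 4 samples per group. G0s2 encodes an inhibitor of adipose triglyceride lipase, and Rgs16 encodes a regulator that speeds the shut-off of heterotrimeric G proteins. The design asks how knockdown of each gene alters the liver transcriptome relative to the shLacZ control. Total counts per sample were 25636504 to 26472233 in shLacZ, 18458266 to 26031061 in shG0s2 and 24855361 to 27170443 in shRgs16. Major urinary protein genes took 10.5% ± 0.643 of counts in shLacZ, 1.15% ± 0.311 in shG0s2 and 2.28% ± 0.896 in shRgs16 (SD, n = 4 each). Mitochondrially encoded genes took 6.19% ± 0.262, 5.52% ± 0.200 and 7.24% ± 0.346 in the same order. Alb, the albumin gene, took 2.80% ± 0.24, 4.13% ± 0.78 and 4.34% ± 0.28. This hepatocyte marker was thus higher on average in both knockdowns as a share of the library total, which is not scaled by TMM. In a principal component analysis of 16018 genes the first component held 57.0% of the variance and the next 16.7%.

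**Figure D1:**
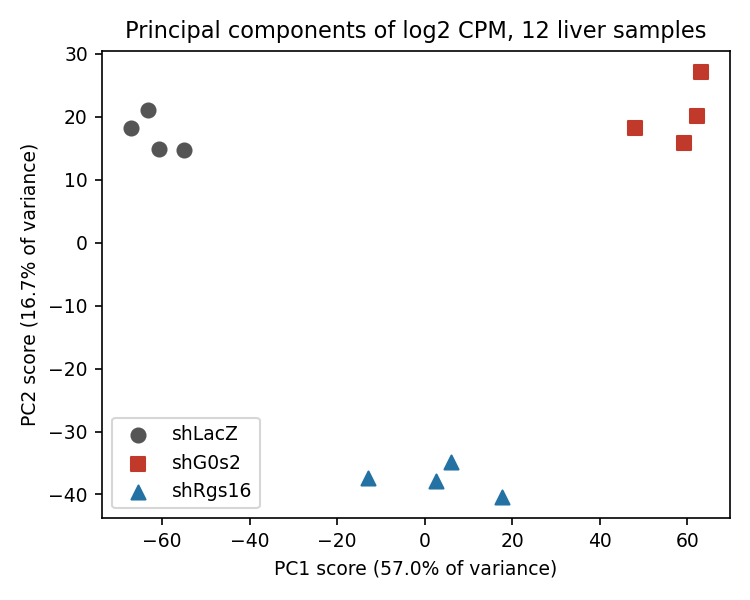
Scores of the 12 samples on the first and second principal components of log2 CPM, each point being a sample. The shLacZ samples lie between −67.1 and −54.9 on the first component, the shRgs16 samples between −13.0 and 17.6 and the shG0s2 samples between 48.0 and 63.2, and the shRgs16 samples lie apart on the second component, between −40.3 and −34.8.

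G0s2 was lower in shG0s2 and Rgs16 was lower in shRgs16 than in shLacZ, and the shG0s2 samples also had less Rgs16. G0s2 (ENSMUSG00000009633; chromosome 1, 193272161 to 193273217, minus strand, GRCm38) averaged 73.7 ± 9.80 CPM in shLacZ, 37.2 ± 10.1 in shG0s2 and 75.0 ± 14.1 in shRgs16 (SD, n = 4 each). Rgs16 (ENSMUSG00000026475; chromosome 1, 153740349 to 153745468, plus strand) averaged 149 ± 46.3, 59.1 ± 11.4 and 26.2 ± 10.9 CPM. The 4 shLacZ samples had 87.4, 74.2, 66.6 and 66.6 CPM of G0s2, and the shG0s2 samples 49.3, 37.9, 24.6 and 37.0. For Rgs16 the shLacZ samples had 105, 212, 153 and 126 CPM, the shG0s2 samples 71.3, 59.0, 43.9 and 62.2, and the shRgs16 samples 14.4, 19.7, 37.4 and 33.3. In the edgeR test G0s2 fell in shG0s2 with a log2 fold change of −0.98 (SE 0.198, adjusted p 0.00301), and Rgs16 fell in shRgs16 by 2.51 (SE 0.378, adjusted p 0.00172). Rgs16 also fell by 1.32 in shG0s2 (SE 0.244, adjusted p 0.00236), while G0s2 in shRgs16 differed by 0.02 (SE 0.145, adjusted p 0.909). The fall of G0s2 depends on scaling: with library size alone its log2 fold change was −0.48 with an adjusted p of 0.0553, against a range of 9.3e-08 to 0.0139 over the other alternatives. In the authors' deposited TPM, G0s2 was 115 ± 14.2 in shLacZ and 95.9 ± 26.8 in shG0s2 (n = 4 each), with ranges that overlap.

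**Figure D2:**
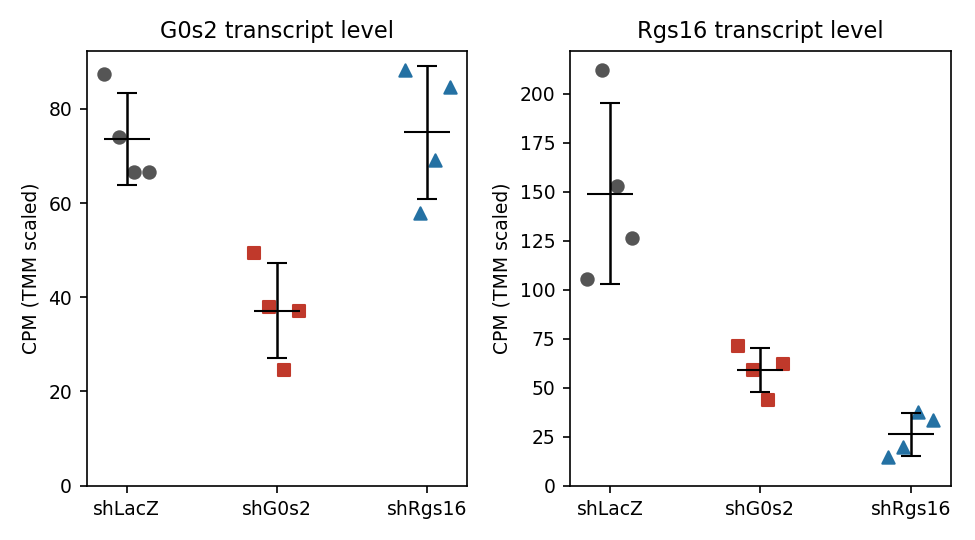
G0s2 and Rgs16 transcript levels in TMM-scaled CPM, where each point is a sample, the horizontal mark the group mean and the bar the SD (n = 4). G0s2 is lower in shG0s2 (24.6 to 49.3 CPM) than in shLacZ (66.6 to 87.4 CPM), and Rgs16 is lower in both knockdowns.

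Relative to shLacZ, shG0s2 livers had higher transcript levels of proliferation and matrix genes and lower levels of male-biased and hepatocyte genes. All 40 genes of the cell cycle list rose (median log2 fold change 2.03), among them Ccnd1, the gene of cyclin D1, from 20.6 ± 0.792 to 138 ± 22.1 CPM. Of 29 extracellular matrix and fibrosis genes 27 rose and 1 fell, while all 25 male-biased genes fell. The steroid-metabolising gene Hsd3b5, which is transcribed mainly in male liver, went from 88.7 ± 19.2 to 0.219 ± 0.108 CPM (n = 4 each). Of 15592 genes tested by edgeR, 4874 rose and 4556 fell, and 2990 of them changed by a fold of 2 or more (2175 up, 815 down). Scaling by library size alone moved the median of all genes by 0.49 on the log2 scale and gave 10067 higher and 1246 lower genes, so that 89.0% of calls were higher against 51.7% with TMM. Changes are therefore stated relative to the bulk of genes, since the labels name no external standard.

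Among the largest increases in shG0s2 was H19, an imprinted non-coding RNA abundant in foetal liver, with a log2 fold change of 7.64 (SE 0.633, adjusted p 5.1e-05). The fatty acid elongase gene Elovl7 rose by 5.66 (SE 0.171, adjusted p 7.9e-10), and Lrtm2 by 6.99 (SE 0.600). Krt20, a keratin gene, had 0 counts in every shLacZ sample and 411 counts over the shG0s2 group. With library size alone it was at least 152.8-fold higher against a floor of 3 counts over the control group. That scaling sets the median gene 0.49 higher on the log2 scale than TMM does, so the bound is lower with TMM. Kcnj14 and Ano3 reached 2.65 ± 1.86 and 2.31 ± 1.29 CPM from 0.0108 CPM each, where shLacZ replicate 3 held the only read and the other shLacZ samples had 0. Apela, which encodes a ligand of the apelin receptor, rose by 6.27, or 7.34 without shLacZ replicate 2, and Sprr1a by 5.94, or 7.55 without shLacZ replicate 1. Moxd1 had a log2 fold change of −9.27 (SE 0.836), or −11.80 without shG0s2 replicate 1, and Hsd3b5 fell by 8.58 (SE 0.274, adjusted p 3.7e-08). The other large decreases were Mup7 (−8.11), Mup17 (−8.10), Mup15 (−8.09), Mup1 (−7.94), Mup12 (−7.88) and Mup19 (−7.39), genes of excreted pheromone-binding proteins whose near-identical copies make each value uncertain. Without shG0s2 replicate 3 the values of Mup17, Mup15, Mup12 and Mup19 were −8.77, −9.09, −8.53 and −8.43.

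The proliferation genes of shG0s2 included Mcm5, a subunit of the replicative helicase, which rose by 2.19 (SE 0.0900), and Ccnd1, which rose by 2.74 (SE 0.106). Camera called the cell cycle list higher with the preset correlation (adjusted p 2.9e-17), but not with an estimated one (adjusted p = 0.257 with an estimated correlation). Matrix genes included Col5a2, which rose by 2.83, and Col4a1, by 1.86 (adjusted p = 0.273 for that list with an estimated correlation). Of 23 genes induced by p53 or DNA damage 17 rose and 0 fell (adjusted p = 0.430 with an estimated correlation), with Tnfrsf10b, a death receptor gene, at 2.59 and Ckap2 at 3.01. Of 25 genes of oxidative stress and NRF2, the transcription factor of antioxidant defence, 17 rose and 6 fell (adjusted p = 0.273 with an estimated correlation), or 19 and 2 with library size alone. Cbr3, a carbonyl reductase gene, rose by 5.16 and the exporter gene Abcc4 by 3.45. These 4 lists gave the same counts when adjusted over the list alone.

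Sex-biased liver genes moved in opposite directions in shG0s2. The 25 male-biased genes had a median of −3.73 (adjusted p = 0.282 with an estimated correlation), with Ugt2b1, a glucuronosyltransferase gene, at −1.74 (SE 0.106). Of 14 tested female-biased genes 10 rose and 0 fell, with a median of 1.55 (adjusted p = 0.324 with an estimated correlation). The cytochrome P450 gene Cyp2b9 rose from 2.78 ± 1.11 to 99.97 ± 14.4 CPM and Rtn4 from 99.6 ± 5.31 to 225 ± 12.6 (n = 4 each). Counts were the same when adjusted over the list alone.

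Metabolic lists of shG0s2 moved in both directions and depended on scaling. All 34 genes of oxidative phosphorylation, the mitochondrial respiratory chain, fell with TMM (median −0.54; adjusted p = 0.273 with an estimated correlation), but with library size alone 5 fell and 3 rose (median −0.05). Ndufb10 and Ndufs3, complex I subunit genes, fell by 0.85 and 0.70. Of 40 genes of fatty acid oxidation and PPARα targets 7 rose and 21 fell (median −0.37; adjusted p = 0.595 with an estimated correlation), a median that became 0.12 with library size alone, when 19 rose and 6 fell. Ucp2 rose by 1.29 and Aldh3a2 by 0.86. Of 25 fatty acid and triglyceride synthesis genes 6 rose and 10 fell and the list was not called by camera (adjusted p 0.439), its median going from −0.10 to 0.39 with library size alone. Lpin1 and Dgat2, which act in triglyceride assembly, fell by 1.79 and 0.93. Of 23 lipid droplet and lipolysis genes 6 rose and 11 fell (camera adjusted p 0.376), with Cidec, a lipid droplet protein gene, at 1.85 and the carboxylesterase gene Ces1f at −1.16. That list's median was −0.07, its mean 0.01 and its median with library size alone 0.41.

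For glucose metabolism in shG0s2, 7 of 26 glycolysis and ChREBP target genes rose and 9 fell (camera adjusted p 0.423), with a median of −0.17 that became 0.32 with library size alone. Pkm, a pyruvate kinase gene, rose by 1.71. Of 24 gluconeogenesis and glycogen genes 3 rose and 15 fell (adjusted p = 0.444 with an estimated correlation), and with library size alone 7 rose and 6 fell. Ppp1r3b, which directs glycogen synthesis, fell by 1.15, and Phkg2, a phosphorylase kinase subunit gene, by 0.54. Of 20 circadian clock genes 0 rose and 11 fell (median −0.39; adjusted p = 0.299 with an estimated correlation), but with library size alone 5 rose and 4 fell, with a median of 0.10. Hlf and Tef, clock-output transcription factor genes, fell by 0.89 and 0.57; with library size alone the Tef value of −0.08 was not past the threshold, nor was Phkg2 at −0.05. Of 30 tested genes of RGS proteins and G protein signalling 16 rose and 4 fell (adjusted p = 0.273 with an estimated correlation), or 24 and 2 with library size alone, with the G protein subunit gene Gnb1 at 1.09 and Rgs2 at 1.28. Adjusted over the list alone, 16 gluconeogenesis genes fell, and the other metabolic, clock and signalling lists gave the counts above.

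Cell type markers of shG0s2 did not move alike. Of 19 hepatocyte markers 0 rose and 16 fell (median −0.93; adjusted p = 0.430 with an estimated correlation), or 3 and 11 with library size alone (median −0.45), with Hpd, a tyrosine-degrading enzyme gene, at −1.74 and the transcription factor gene Hnf4a at −0.96. Of 20 Kupffer cell and macrophage markers 18 rose and 0 fell (adjusted p = 0.324 with an estimated correlation), with Trem2 at 2.66 and the cathepsin gene Ctss at 1.12. Of 33 T and NK cell markers 28 rose and 1 fell (adjusted p = 0.496 with an estimated correlation). Pdcd1, the gene of the receptor PD-1, rose by 2.43, and Cd4 was the gene that fell, by 1.59. Of 18 stellate cell and fibroblast markers 16 rose and 2 fell (adjusted p = 0.343 with an estimated correlation), with the growth factor receptor gene Pdgfrb at 2.21 and Tcf21 at 2.17. Of 19 endothelial markers 2 rose and 3 fell and camera did not call the list (adjusted p 0.969, median 0.07, mean −0.02), but with library size alone 15 rose and 1 fell (median 0.56, against 1.60 for the stellate markers). Ehd3 fell by 0.85, and Oit3 fell by 0.40 with TMM but was 0.08 with library size alone. The counts were the same when adjusted over the list alone.

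Relative to shLacZ, shRgs16 livers also had higher transcript levels of proliferation and matrix genes and lower levels of male-biased genes. Of 40 cell cycle genes 35 rose and 0 fell (median 1.37), and Ccnd1 went from 19.3 ± 0.743 to 43.8 ± 5.35 CPM (n = 4 each). Of 29 matrix and fibrosis genes 25 rose and 0 fell, and of 25 male-biased genes 23 fell and 0 rose, with Mup20, which encodes the male pheromone darcin, going from 20761 ± 1244 to 3351 ± 513 CPM. The glutathione transferase gene Gstm1 rose from 391 ± 55.8 to 1820.0 ± 187 CPM. Of 15325 genes tested by edgeR, 3769 rose and 3749 fell, and 1536 changed by a fold of 2 or more (1079 up, 457 down). Library size alone moved the median of all genes by 0.30 and gave 7686 higher and 1279 lower genes, 85.7% of calls being higher against 50.1% with TMM.

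H19 was among the largest increases in shRgs16 as well, at 7.12 (SE 0.394, adjusted p 1.4e-05). The calcium channel gene Cacna1b rose by 6.21 (SE 0.444) and Tmc5 by 5.17 (SE 0.544). Afp, the gene of alpha-fetoprotein, rose from 1.43 ± 0.231 to 29.5 ± 17.8 CPM (log2 fold change 4.37, adjusted p 0.00046). The foetal growth factor gene Igf2 rose by 4.58, or 3.97 without shRgs16 replicate 2, and Akr1b7 by 4.77, or 5.63 without shLacZ replicate 4. Amy2a3, a pancreatic amylase gene with near-identical copies, reached 26.2 ± 15.9 CPM from 0.0216. Moxd1 fell by 6.18 (SE 0.703), Mup21 by 4.98, Mup9 by 3.71 and Mup8 by 3.57, the Mup values being uncertain for each copy. Mup17 fell by 3.66 (adjusted p 0.0205), or by 4.58 without shRgs16 replicate 3, and lost its call without shRgs16 replicate 1 (−3.64) or replicate 4 (−3.47). The cilium gene Cfap53 fell by 3.90, the potassium channel gene Kcnk1 by 3.65, or 4.36 without shRgs16 replicate 3, and Hectd2os by 3.38, the last an opposite-strand transcript that cannot be told from its neighbour when strand use is not stated.

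The cell cycle list was called higher in shRgs16 with the preset correlation (adjusted p 1.9e-13) but not otherwise (adjusted p = 0.290 with an estimated correlation), and Ube2c, a mitotic ubiquitin-conjugating enzyme gene, rose by 2.29 beside Ccnd1 at 1.18. For the matrix list (adjusted p = 0.335 with an estimated correlation), Mmp2, a gelatinase gene, rose by 1.86 and Loxl1, a collagen cross-linking enzyme gene, by 2.05. Of 23 p53 and DNA damage genes 9 rose and 2 fell and the list was not called (camera adjusted p 0.0535), or 12 and 0 with library size alone, with Psrc1 at 2.68 and Zmat3 at 0.53. Of 25 NRF2 and oxidative stress genes 13 rose and 7 fell, also not called (camera adjusted p 0.0518), or 16 and 2 with library size alone, with Gstm1 at 2.22 and the haem oxygenase gene Hmox1 at 1.25. When adjusted over the list alone, 9 p53 genes rose and 1 fell, 14 NRF2 genes rose and 7 fell, and the cell cycle and matrix counts were the same.

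Among sex-biased genes of shRgs16, the male-biased list had a median of −1.66 (adjusted p = 0.290 with an estimated correlation) and Cyp4a12b, 1 of several similar P450 genes, fell by 1.02. Of 13 tested female-biased genes 8 rose and 0 fell, with a median of 1.04 (adjusted p = 0.290 with an estimated correlation). The transporter gene Slc22a27 rose by 3.16 (SE 0.186) and Cyp3a44, which has close copies, by 4.28 (SE 0.416). The counts adjusted over the list alone were 25 lower for male-biased genes and 8 higher for female-biased genes.

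In shRgs16, 33 of 34 oxidative phosphorylation genes fell and 0 rose with TMM (median −0.34; adjusted p = 0.290 with an estimated correlation), while with library size alone 8 fell and 1 rose (median −0.04). Sdhc fell by 0.50 and Ndufb5 by 0.53. Of 40 fatty acid oxidation and PPARα target genes 10 rose and 20 fell and the list was not called (camera adjusted p 0.123), its median going from −0.19 to 0.11 with library size alone. Pdk4, a kinase that limits pyruvate oxidation, rose by 3.12 and the peroxisome gene Pex11a fell by 0.91. Of 25 fatty acid and triglyceride synthesis genes 4 rose and 13 fell, not called by camera (adjusted p 0.0535), or 6 and 6 with library size alone, with the acyltransferase gene Agpat2 at −0.88 and the citrate carrier gene Slc25a1 at −0.62. Of 22 lipid droplet and lipolysis genes 5 rose and 7 fell (camera adjusted p 0.366; median −0.10, or 0.19 with library size alone), with Aadac at −0.69 and Bscl2, the gene of seipin, at −0.56. In counts adjusted over the list alone, 12 oxidation genes rose and 20 fell, and the other counts were the same.

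Of 26 glycolysis and ChREBP target genes 6 rose and 11 fell in shRgs16 (camera adjusted p 0.257), with a median of −0.13 that became 0.17 with library size alone. Pkm rose by 1.11. Of 24 gluconeogenesis and glycogen genes 3 rose and 11 fell (camera adjusted p 0.202), with a median of −0.16 that became 0.14 with library size alone; the kinase gene Sik1 rose by 1.10 and Ppp1r3b fell by 0.91. Of 20 clock genes 0 rose and 10 fell (median −0.42; adjusted p = 0.541 with an estimated correlation), but with library size alone 7 rose and 6 fell (median −0.13). Per3 fell by 0.56 and Per1 by 0.46, the latter not past the threshold with library size alone (−0.16). Of 28 RGS and G protein signalling genes 9 rose and 8 fell (camera adjusted p 0.507; median 0.05), while with library size alone 17 rose and 4 fell (median 0.36), with Gcgr, the glucagon receptor gene, at −0.79 and Gnb1 at 0.83. Adjusted over the list alone, the counts were 6 and 12 for glycolysis, 5 and 11 for gluconeogenesis, 0 and 11 for the clock and 9 and 8 for G protein signalling.

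Of 19 hepatocyte markers 2 rose and 11 fell in shRgs16 (median −0.39; adjusted p = 0.565 with an estimated correlation), while with library size alone 7 rose and 5 fell (median −0.09); the antitrypsin gene Serpina1b, which has close copies, was at −0.93. Of 19 Kupffer cell and macrophage markers 17 rose and 0 fell (adjusted p = 0.290 with an estimated correlation), with Cd68 at 1.14 and the complement gene C1qa at 0.71. Of 33 T and NK cell markers 27 rose and 1 fell (adjusted p = 0.501 with an estimated correlation), with the granzyme gene Gzma at 1.59 and Pdcd1 at 1.74. Of 19 endothelial markers 9 rose and 0 fell (adjusted p = 0.659 with an estimated correlation), or 17 and 0 with library size alone, with Egfl7 at 0.54 and Pecam1 at 0.48. Of 18 stellate cell and fibroblast markers 9 rose and 4 fell, a list not called by camera (adjusted p 0.221), or 12 and 3 with library size alone, with Pdgfrb at 1.43 and Nes, the gene of nestin, at 1.47. Adjusted over the list alone, 3 hepatocyte markers rose and 12 fell, 29 T and NK markers rose and 1 fell, and the other counts were the same.

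**Figure D3:**
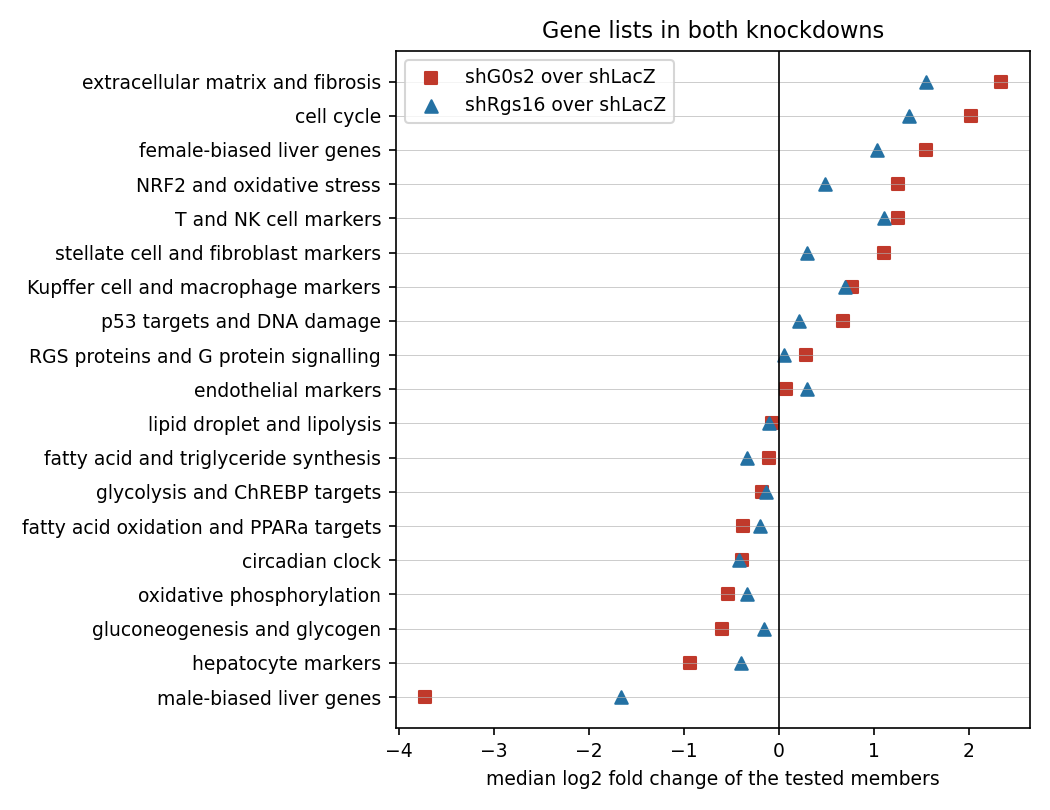
Median log2 fold change of the tested members of 19 gene lists in shG0s2 over shLacZ (squares) and shRgs16 over shLacZ (triangles), TMM-scaled. Matrix genes (2.34 and 1.55) and male-biased genes (−3.73 and −1.66) mark the ends, and library size alone moves all genes up by 0.49 and 0.30, which turns several of the medians just below 0 positive.

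Across the list tests, camera with the preset correlation called 29 of 44 lists in shG0s2 (15 higher, 14 lower) and 20 of 44 in shRgs16 (12 higher, 8 lower). With estimated correlations it called 0 in either comparison, the lowest adjusted p being 0.257 and 0.290, while 7 and 6 lists had an unadjusted p under 0.05; fry, which does not compare a list with other genes, called 36 and 28. Between the knockdowns it called 19 lists with the preset correlation (7 higher and 12 lower in shG0s2) and 0 with estimated ones, with a lowest adjusted p of 0.105 and 4 lists with an unadjusted p under 0.05.

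The direct comparison of the knockdowns showed a stronger loss of male-biased transcripts and more proliferation and stellate cell transcripts in shG0s2 than in shRgs16. Of 25 male-biased genes 20 were lower and 1 was higher in shG0s2, with Hsd3b5 at 0.220 ± 0.109 CPM against 25.03 ± 18.4 (n = 4 each). Cyp2b9 was 101 ± 14.7 CPM in shG0s2 and 3.07 ± 0.537 in shRgs16, a log2 difference of 5.04 (SE 0.206, adjusted p 1.4e-08). Of 40 cell cycle genes 30 were higher and 0 lower, of 18 stellate markers 13 higher and 1 lower, and of 19 endothelial markers 0 higher and 11 lower (median −0.34), a count that fell to 4 lower with library size alone (median −0.14). Of 16018 genes tested, 3359 were higher and 3281 lower in shG0s2, with 1270 differing by a fold of 2 or more (749 higher, 521 lower). Library size alone shifted the median by 0.20 and gave 6054 higher and 1568 lower genes, 79.4% of calls being higher against 50.6%.

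Relative to shRgs16, and adjusted over the list alone, shG0s2 had 21 male-biased genes lower and 1 higher, 32 cell cycle genes higher, 13 stellate markers higher and 1 lower, and 13 endothelial markers lower. These lists were called with the preset correlation, and with an estimated correlation their adjusted p was 0.516 for male-biased genes, 0.516 for the cell cycle, 0.324 for stellate markers and 0.599 for endothelial markers. G0s2 was lower by a log2 difference of −1.01 (SE 0.203, adjusted p 0.00237) and Rgs16 higher by 1.18 (SE 0.329, adjusted p 0.0169). Slc1a1, a glutamate transporter gene, was higher in shG0s2 by 5.42 (SE 0.372). Nudt11 had 2.34 ± 0.444 CPM against 0.0366 ± 0.0505 and Kcnj14 had 2.67 ± 1.89 against 0.0597 ± 0.119, the log2 difference of Nudt11 going from 5.78 to 7.03 without shRgs16 replicate 1. That of Kcnj14 was 5.42, or 4.84 without shG0s2 replicate 2, and the shRgs16 samples other than replicate 4 had 0 CPM of it. Amy2a3, with 0.0391 ± 0.0457 CPM in shG0s2 and 28.5 ± 17.2 in shRgs16, and Slc24a4 with 0.0941 ± 0.113 and 3.89 ± 1.55 were lower in shG0s2. Hsd3b5 differed by −6.74, or −6.09 without shRgs16 replicate 3, and Slc24a4 by −5.33, or −6.55 without shG0s2 replicate 4.

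**Figure D4:**
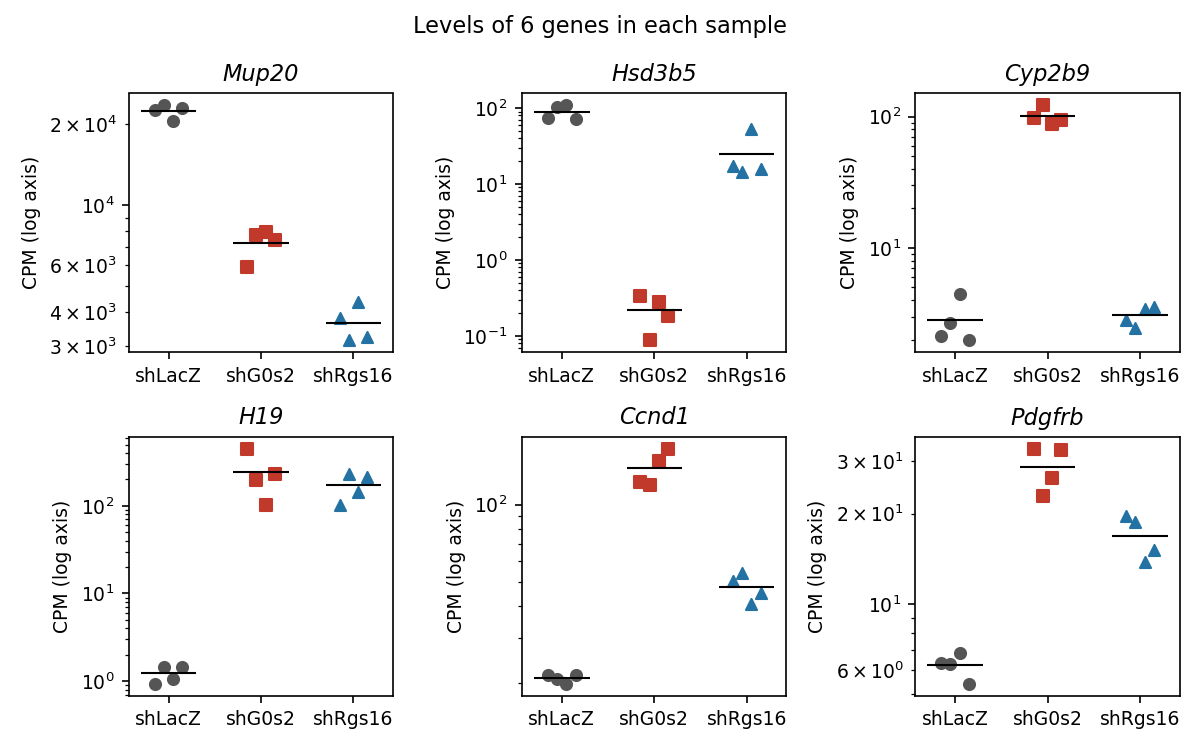
TMM-scaled CPM of Mup20, Hsd3b5, Cyp2b9, H19, Ccnd1 and Pdgfrb on log axes, each point a sample and each line a group mean (n = 4), for genes picked for display after their values were seen. The mean of Cyp2b9 is 101 CPM in shG0s2 and 3.07 in shRgs16, while H19 is higher in every sample of both knockdowns than in shLacZ.

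Many genes moved the same way in both knockdowns. H19 (7.64 in shG0s2 and 7.12 in shRgs16), Igf2 (4.77 and 4.58), Bmp8b, a growth factor gene (5.35 and 4.29), and Cacna1b (4.16 and 6.21) rose most in both, and Mup17, Mup9 (−6.06 and −3.71), Mup21 (−6.38 and −4.98) and Moxd1 fell most. The Igf2 value of 4.77 in shG0s2 was 4.06 without shG0s2 replicate 1, and with limma-voom it was 4.54 and not past the threshold (adjusted p 0.0506). Among 15148 genes tested in both comparisons, 2863 rose in both and 2682 fell in both, where independent gene sets would share 1127 and 1126, and 141 and 121 were called in opposite directions. Unchanged groups simulated against the same controls shared 0 increases and a mean of 0.05 decreases over 20 draws, but as they had a mean of only 0.55 and 0.3 called genes, that overlap was near 0 by construction and is no measure of sharing. With the controls divided between the comparisons, 1969 to 2194 genes rose and 1869 to 2089 fell in both. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.464, against 0.0200 in the simulations and 0.470 to 0.488 with divided controls. The correlation was 0.772 (simulated 0.503, divided controls 0.658 to 0.687) and 78.1% of genes had the same sign (simulated 66.6%).

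The authors' deposited table called 3376 genes in shG0s2 (2426 up, 950 down), all of which met an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Of these, 2936 were tested here, 2914 were called in the same direction at a fold of 2 or more and 0 in the opposite direction. For shRgs16 the authors' deposited table called 1767 (1224 up, 543 down), of which 1514 were tested here, 1499 were called in the same direction at a fold of 2 or more and 0 in the opposite direction.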

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

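Per-sample CPM of named genes (TMM over all 12 samples), total counts and the Mup and mitochondrial shares were examined in 308 groups of 4 values. In 22 of them a sample stood far from the other 3 relative to the range of the group. Chance gives about 1 in 20 such groups, and the 22 were spread over the groups, with 8 in shLacZ, 6 in shG0s2 and 8 in shRgs16.

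In shLacZ, replicate 3 was the highest for Kcnj14 (0.0442 CPM) and Ano3 (0.0442 CPM), each with 0 in the other samples, and for Psrc1 (0.884 CPM, others 0.283 to 0.372). Replicate 1 was the highest for Sprr1a (1.30 CPM, others 0 to 0.221). Replicate 4 was the lowest for Ehd3 (65.1 CPM) and Hmox1 (29.0 CPM) and the highest for Akr1b7 (0.612 CPM) and Cyp4a12b (225 CPM).

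In shG0s2, replicate 3 was the highest for Mup21 (6.00 CPM), Mup9 (62.0 CPM) and Mup8 (42.2 CPM, others 6.03 to 8.58) and the lowest for Egfl7 (22.3 CPM). Replicate 1 was the highest for Moxd1 (1.04 CPM, others 0 to 0.131). Replicate 2, the sample with the lowest total count, was the lowest for Hlf (32.3 CPM).

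In shRgs16, replicate 3 was the highest for Hsd3b5 (52.5 CPM, others 14.5 to 17.1). Replicate 2 was the highest for Lrtm2 (0.837 CPM), Apela (0.8002 CPM) and Slc24a4 (6.18 CPM) and the lowest for Ppp1r3b (108.8 CPM). Replicate 4 was the highest for Kcnj14 (0.239 CPM, others 0) and Slc22a27 (22.4 CPM) and the lowest for Gstm1 (1670.0 CPM, others 2053 to 2094).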

How the results depend on the processing

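Leaving out the Mup genes was chosen after the data were seen, and all other alternatives before. Under DESeq2, limma-voom, relative log expression scaling, no filter, the stricter filter, all 12 samples in the model and the Mup genes left out, the counts of changed genes stayed within 1.5 times the reported ones. DESeq2 called 9584 genes in shG0s2, of which 9051 were shared in the same direction, 7543 (7179 shared) in shRgs16 and 6746 (6426 shared) between the knockdowns. Without the Mup genes 9389 and 7456 genes were called against shLacZ. Leaving out 1 sample gave 8764 to 9303 genes in shG0s2, 6487 to 7397 in shRgs16, 5780 to 6863 between the knockdowns, and 28 to 30 and 19 to 25 lists. With DESeq2 lists 5494 genes changed in both knockdowns, and at an adjusted p under 0.1 6486. The changes of pseudocount were not run, since the tables hold counts.

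Library size alone turned the balance of calls, with 10067 higher and 1246 lower in shG0s2, 7686 and 1279 in shRgs16, and 6054 and 1568 between the knockdowns, because its construction leaves in the median shifts of 0.49, 0.30 and 0.20. It brought G0s2 in shG0s2 to −0.48, and changed the sign of Rps18 (0.17), Rps27 (0.17), Oit3 (0.0813) and Lipe (0.049) in shG0s2 and of mt-Nd1 (0.0153) in shRgs16. A fold of 2 or more, which by construction calls fewer genes, left 2990 (2175 higher, 815 lower), 1536 (1079, 457) and 1270 (749, 521). With estimated correlations camera called 0 lists in shG0s2 and 0 in shRgs16, against 36 and 28 by fry, a test without the comparison with other genes, and the stricter filter gave 29 and 19. Over all alternatives 22 values of named genes other than G0s2 and Rgs16 lost their call and 5 changed sign. In addition, G0s2 in shG0s2 lost its call with library size alone.

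With the replicate number as a block, 9298, 7104 and 6536 genes and 29 and 20 lists were called. The numbers do not pair the samples: same-numbered samples of different groups correlated at −0.074 to 0.136 in their deviations from the group means, and 4 of 12 such pairs correlated best with their own number. Under the block Mup17 (−4.38) and the erythroid gene Slc4a1 (1.01) in shRgs16 were not past the threshold. Depth limits genes with few reads: a gene with 0 counts in a group is bounded only by 3 counts.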

Other observations

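Immune and stress lists beyond those in the report also moved. In shG0s2, 20 of 29 inflammation and chemokine genes rose and 3 fell (adjusted p = 0.324 with an estimated correlation), and in shRgs16 17 of 27 rose and 1 fell (adjusted p = 0.290 with an estimated correlation). Interferon response genes numbered 21 higher and 1 lower of 44 in shG0s2 (adjusted p = 0.646 with an estimated correlation) and 14 and 3 in shRgs16, where camera did not call the list (adjusted p 0.0956). Antigen presentation genes numbered 13 higher and 3 lower of 24 (adjusted p = 0.605 with an estimated correlation) and 12 and 2 (adjusted p = 0.727 with an estimated correlation). Dendritic cell markers rose in 9 of 12 and 7 of 12 (adjusted p = 0.294 and 0.290 with an estimated correlation), and cholangiocyte markers in 10 of 14 and 8 of 14 (adjusted p = 0.443 and 0.380). B cell markers numbered 5 higher of 19 in shG0s2, not called, and 7 higher and 1 lower in shRgs16 (adjusted p = 0.290 with an estimated correlation). Monocyte and neutrophil markers numbered 6 higher of 19 in shG0s2 (adjusted p = 0.507 with an estimated correlation) and 4 in shRgs16, not called. Immediate early genes numbered 10 higher and 2 lower of 23 in shG0s2, not called, and 12 and 1 of 22 in shRgs16 (adjusted p = 0.290 with an estimated correlation). Replication-dependent histone genes fell in 11 of 12 in shG0s2 (median −1.49; adjusted p = 0.273 with an estimated correlation) and 8 of 12 in shRgs16 (median −1.05; adjusted p = 0.335), although the cell cycle list rose. With library size alone, the counts in shG0s2 and shRgs16 were 40 and 0, and 21 and 0 for interferon genes, 22 and 0, and 18 and 0 for antigen presentation, 24 and 1, and 22 and 0 for inflammation, 11 and 0, and 12 and 0 for dendritic cells, 13 and 0, and 10 and 0 for cholangiocytes, 10 and 0, and 14 and 1 for B cells, 14 and 0, and 7 and 0 for monocytes and neutrophils, 15 and 0, and 15 and 0 for immediate early genes, and 0 and 10, and 0 and 8 for histones. Counts adjusted over the list alone were the same except in shG0s2 for interferon (18 and 1), B cell (3 and 0), cholangiocyte (10 and 1) and immediate early genes (9 and 2), and in shRgs16 for interferon (12 and 3), antigen presentation (12 and 4), inflammation (19 and 1), dendritic cell (9 and 0) and histone genes (0 and 9).

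Liver function lists mostly held lower genes with TMM. Acute phase and complement genes numbered 3 higher and 19 lower of 28 in shG0s2 (median −0.83; adjusted p = 0.507 with an estimated correlation) and 4 and 7 in shRgs16, not called (median −0.04, or 0.26 with library size alone). Endoplasmic reticulum stress genes numbered 1 higher and 18 lower of 29 in shG0s2 (adjusted p = 0.444 with an estimated correlation), a median of −0.45 that became 0.04 with library size alone, and 2 and 21 in shRgs16 (median −0.61; adjusted p = 0.335). Bile acid genes numbered 4 and 13 of 21 (adjusted p = 0.444 with an estimated correlation) and 5 and 12, not called (7 and 6 with library size alone). Lipid uptake and lipoprotein genes numbered 7 and 19 of 28 in shG0s2 (adjusted p = 0.444 with an estimated correlation; median −0.47, or 0.02 with library size alone) and 5 and 15 in shRgs16 (adjusted p = 0.290; median −0.37), or 10 and 9, and 9 and 10 with library size alone (shRgs16 median −0.06). Mitochondrially encoded genes fell in 10 of 12 in shG0s2 (median −0.74; adjusted p = 0.257 with an estimated correlation) and 3 of 12 in shRgs16, not called (median −0.12, or 0.18 with library size alone). Periportal genes numbered 3 and 16 of 22 in shG0s2 (adjusted p = 0.507 with an estimated correlation) and 4 and 8 in shRgs16, not called (median −0.10, or 0.21 with library size alone). Xenobiotic metabolism genes numbered 8 and 19 of 30 in shG0s2 (adjusted p = 0.444 with an estimated correlation; median −0.49, mean 0.05) and 6 and 9 of 29 in shRgs16, not called (median −0.05, mean 0.02); with library size alone they numbered 10 and 11 in shG0s2 and 12 and 5 in shRgs16 (median 0.25). Ketogenesis genes numbered 2 and 4 of 7 in shG0s2, not called (median −0.31, or 0.18 with library size alone), and 1 and 5 in shRgs16 (adjusted p = 0.290 with an estimated correlation). Camera called neither comparison for cholesterol synthesis (2 and 9 of 25; 2 and 6; with library size alone 17 and 2; 8 and 3), ribosomal proteins (1 and 12 of 37; 2 and 8; with library size alone 36 and 0; 30 and 2), pericentral genes (3 and 8 of 20; 4 and 3) or glucocorticoid-responsive genes (5 and 8 of 18; 5 and 5). The same held for erythroid (8 and 1 of 11; 2 and 1 of 9), pancreas and adipose (1 and 2 of 5; 4 and 1), gall bladder and gut (3 and 2 of 7; 2 and 2 of 6) and abundant non-coding RNA lists (1 and 3 of 9; 2 and 1 of 10). Library size alone also turned the medians of pericentral (−0.20 to 0.29), glucocorticoid-responsive (−0.40 to 0.09), pancreas and adipose (−0.44 to 0.05) and gall bladder genes (−0.11 to 0.38) in shG0s2 and of non-coding RNAs (−0.18 to 0.14) in shRgs16. The counts with library size alone were 7 and 14 for acute phase, 0 and 6 for mitochondrially encoded and 7 and 12 for periportal genes in shG0s2, and 4 and 14 for endoplasmic reticulum stress, 2 and 2 for ketogenesis, 8 and 2 for pericentral, 8 and 3 for glucocorticoid-responsive and 6 and 1 for erythroid genes in shRgs16. Adjusted over the list alone, the counts differed in shG0s2 for bile acid (4 and 14), lipid uptake (8 and 19), cholesterol (2 and 6), ribosomal (1 and 8) and non-coding genes (0 and 2), and in shRgs16 for bile acid (6 and 13), lipid uptake (5 and 17), mitochondrially encoded (0 and 2), ribosomal (1 and 4) and erythroid genes (0 and 1). The cholesterol medians were 0.01 and 0.02 and the means −0.04 and −0.03, and camera's direction opposed the median for cholesterol and gall bladder genes in both comparisons, for endothelial markers in shG0s2 and for non-coding RNAs in shRgs16.

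Of the tests that follow, those of hepatocyte share, female libraries and Mup copies were chosen after the result was seen. The words CAAGACA and ATGGCCT were picked as the lowest of all words in these same data. Their follow-up tests therefore concern words chosen for being extreme. Other splits of the samples were counted for each result. Of the 35 splits of 8 samples into 4 and 4, only the real 1 gave as many changed genes in each of the 3 comparisons. The real splits gave 9430, 7518 and 6640 genes, and the highest other split gave 0, 0 and 1. With the real split as 1 of 35, chance is unlikely but not excluded. The other splits mix groups that lie apart, which by itself lowers their counts. Splits also cannot address any other difference that coincides with the groups. Of 100 groupings of the 12 samples, only the real 1 gave as many genes changed in both knockdowns (5545, the highest other 0). For lists, 3 of 35 splits called as many as the real 29 in shG0s2 (highest other 30) and 6 of 35 as many as the real 20 in shRgs16 (highest other 25), so chance is not excluded for the number of lists. The 16 splits that move 1 sample from each group keep much of the real contrast and called 16 to 30 and 12 to 25 lists, against 1 to 14 and 5 to 15 in the 18 splits that move 2.

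Genes moved together in shG0s2 and shRgs16 livers. Chance error in the shared controls does not account for it: with divided controls the covariance was at least 1.013 times that with all controls. Dividing them cannot address a trait common to all shLacZ samples, which would move genes alike in both comparisons and stays open. A lower share of hepatocytes would raise markers of other cell types alike. In shG0s2 the endothelial median lay below the stellate median by a log2 difference of −1.034 (95% interval over 10000 resamples of the genes, −1.54 to −0.48). In shRgs16 these 2 medians were 0.30 and 0.30 (difference −0.01, 95% interval −0.643 to 0.498). The endothelial median there lay below that of T and NK cell markers by −0.816 (99.2% interval, widened for 6 pairs of lists, −1.16 to −0.53). Unequal medians argue against a lower share as the whole account in these samples. The intervals treat genes of a list as independent and carry no spread between samples, so they cannot settle the question. Estimated correlations were 0.30 for endothelial and 0.28 for stellate markers in shG0s2. In shRgs16 they were 0.62 for endothelial and 0.53 for T and NK cell markers. Part of the rise in each group stays open to a lower share. Loss of silencing by miR-122, a liver microRNA, which strong hairpin expression might cause, cannot be told apart from no such loss. Its site ranked 10.5% from the top of all words in shG0s2 and 8.25% in shRgs16. Both lie outside the top 5%, the mark set beforehand against such a loss. However, the 95% intervals around its t of 1.26 and 1.51 reached past the start of the top 5% of words (1.69 and 1.79), and that margin was added to the mark. Of named miR-122 targets with the site, Klf6 (1.93), Slc7a1, Ccng1, Bckdk, Aldoa and Agpat1 rose in shG0s2. P4ha1, Gys1 and Cd320 were not past the threshold. In shRgs16 Klf6 (1.07), Slc7a1, Agpat1, Aldoa and Bckdk rose, and the rest were not past it. So few genes cannot decide the question. Sites of microRNAs of other tissues ranked as high or higher in shG0s2, with miR-124 at 0.043% (t 3.45), miR-1 at 2.73%, miR-9 at 4.29% and miR-133 at 10.2%. In shRgs16 miR-124 (0.977%) and miR-1 (5.88%) ranked higher, while miR-9 (50.8%) and miR-133 (18.9%) ranked lower. A rank near 10% is therefore not particular to a liver microRNA. These ranks were adjusted for length, GC content and expression. Unadjusted, genes with the miR-122 site had a median of 0.145 against 0.022 without it in shG0s2, and 0.110 against 0.017 in shRgs16. That gap was wider than for any other microRNA scored, but the adjusted differences were 0.030 and 0.027. A biological effect shared by both knockdowns stays open, since Rgs16 was lower in both groups with TMM, although its TPM ranges in shLacZ and shG0s2 overlap.

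Most male-biased genes fell (25 of 25 in shG0s2 and 23 of 25 in shRgs16), and the larger part of the tested female-biased genes rose (10 of 14 and 8 of 13). The data hold 20 female-biased genes, and the rest did not pass the filter, which genes near 0 in shLacZ can pass by rising. With an estimated correlation camera called neither list (adjusted p = 0.282 and 0.290 for male-biased genes, 0.324 and 0.290 for female-biased genes). Female animals are excluded, since in 12 of 12 samples Xist was under 1 CPM (highest 0.596) and 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) were above 10 CPM (lowest 13.7). Reads shared among Mup copies do not account for the fall either: the 17 male-biased genes outside that family had a median of −2.812 in shG0s2 (95% interval −3.89 to −1.78), 17 of 17 being lower, and the 49 Mup genes summed to 1 feature fell by 3.68 (SE 0.211, adjusted p 6.5e-08). In shRgs16 the values were −1.15, 15 of 17, and −2.51 (SE 0.302). A biological difference between the knockdown and control groups stays open and was not tested.

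Words of 7 bases in 3′ untranslated regions gave a pattern that may reflect hairpins acting on other transcripts. In shRgs16, genes with CAAGACA were lower by a log2 difference of −0.14 (1685 genes, t −9.04, the lowest of 16372 words), and base composition does not account for it, as the next word with the same bases lay 2.63 units of t away. The word stands in the last exon of Rgs16, exon 5 of 5, in coding sequence at chromosome 1, 153743666 to 153743672 (plus strand, GRCm38), and its context there, GACCAAGACAAAC, also holds CCAAGAC and ACCAAGA, which ranked as the second and the fourth lowest words, but not ACAAGAC, the third lowest (t −6.41). Of the 8-base forms with 1 flanking base, CCAAGACA, which Rgs16 contains, had the lowest t (−6.50, difference −0.17), and CAAGACAT, which it does not, the lowest difference (−0.19, t −6.01). In shG0s2 CAAGACA ranked 7.50% from the lowest, outside the lowest 1%, as pairing with the seed of the Rgs16 hairpin would predict. However, 29.8% of expressed transcripts hold the word, above a bound of 25% that was set after the word was picked but before this share was counted. Seed pairing of the Rgs16 hairpin therefore cannot be told apart from a chance match of the word to Rgs16 without the hairpin sequence. The association itself lay in 3′ untranslated regions (difference −0.15, t −9.02). It was not seen in 2365 genes with the word only elsewhere in the transcript (−0.01, t −0.64). In shG0s2 over shRgs16, which uses the same shRgs16 samples, CAAGACA was the word most associated with higher levels (t 6.61). In shG0s2 the lowest word was ATGGCCT (t −4.81), and 0 G0s2 transcripts contain it, which argues against seed pairing of a hairpin matched to G0s2. ATGGCCT was also within the lowest 1% in shRgs16 (0.849%, t −2.76), and ATCATCC was nearly as low in shG0s2 (t −4.73). The hairpin sequences are not given in the sources used here.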
